A study of Homo sapiens with 10 samples.

How the data were processed

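RNA was taken from neurospheres of the human neural progenitor line ReNcell VM after 6 days of differentiation under treatment, with 6 neurospheres pooled per library. RNA was purified with a Maxwell kit and libraries were made with SureSelect RNA Direct, an exome capture kit, per the labels. The 10 libraries form 5 groups of 2: vehicle (0.1% DMSO), DEP, DProP, DPP and Mix, each treatment labelled 100 µM. All libraries were used.

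The values are raw read counts per NCBI gene identifier, as deposited by the authors, neither normalised nor filtered. The authors' processing notes name Trimmomatic 0.38, FastQC, HISAT2 2.1.0, StringTie 2.1.3b, edgeR 4.0.9, R 4.3.2 and the build GRCh38. Which of these made the counts, the annotation release, the strand setting and the handling of reads that map to several places are not given in the sources used here. The table holds 46427 genes, of which 17765 have no count in any library. Of the identifiers, 44698 matched a RefSeq table. Totals per library ran from 57222381 to 72973100 counts.

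Counts were analysed with edgeR 4.0.16 in R 4.3.3. Genes with enough counts for a test were kept by group (filterByExpr), which left 19465, and libraries were scaled by TMM. A robust quasi-likelihood fit of all 10 libraries with 1 mean per group left 5 residual degrees of freedom. Each treatment was compared with vehicle, and the treatments with one another, in 10 comparisons. Adjusted p values follow Benjamini and Hochberg within a comparison, and the threshold was 0.05 without a fold minimum. CPM values use the TMM factors. The standard error of a log2 fold change is its size divided by the square root of the F statistic. With 2 libraries per group an exact test of a single gene cannot pass the threshold, so the p values rest on the pooled spread of the 5 groups. The common biological coefficient of variation was 9.40%, and the median 95% interval reached 0.26 to each side on the log2 scale.

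Before the data were examined, 38 gene lists were fixed from general knowledge, of which 37 had the 5 tested members needed. The microglia list had 3 and was not tested. Lists were tested with camera of limma 3.58.1 at a preset correlation of 0.01, with camera at an estimated correlation, and with fry. List tests between treatments, a correction for GC content and gene length (a lowess trend per library with a span of 0.3), the removal of rRNA genes and a fit without both vehicle libraries were added after the data were seen.

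Genes were named by a rule fixed before the data were examined. Against vehicle it takes the 8 largest increases and the 8 largest decreases past the threshold, and between treatments 4 of each, with a symbol, a mean of at least 1 CPM and both libraries of a group beyond both of the other. It adds up to 4 members with the smallest p from each called list and from the lists central to the study's questions. For the overlap of the 4 treatments it takes the 10 genes with the largest mean change. The text gives a part of these, and prefers genes whose calls held in every alternative. MALAT1 was chosen after its values were seen.

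Alternatives were relative log expression factors, library size alone, no filter, a stricter filter (1 CPM in 2 libraries), limma-voom, DESeq2 1.42.0, a fit of the 2 compared groups, the replicate number as a block, a 2-fold minimum (1 on the log2 scale) and leaving out each library. The last keeps the other groups, so that a lone library is assumed to vary like them. Replicate numbers do not pair the libraries: correlations of replicate differences between groups ran from -0.0465 to 0.0471 over genes, in 10 pairs of groups. The overlap of the 4 treatments was set beside 20 simulations of unchanged groups with shared controls.

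The tests were checked on simulated data with the design of DEP against vehicle. edgeR called 30.9%, 76.9% and 92.1% of the 68, 65 and 63 genes shifted by 0.5, 1 and 2 on the log2 scale. It called 0.0584% of the 18831 unshifted genes. limma-voom called 27.9%, 70.8% and 84.1% of the shifted genes, and DESeq2 called 36.8%, 77.3% and 86.4%. A list shifted by 0.4 had a camera adjusted p of 5.85e-74, or 0.000186 with an estimated correlation. A simulated GC trend gave 4412 called genes before the correction and 1 after it, while 81.7% of 60 genes with a known 2-fold change were called after it. This trend was linear in GC content and stronger than in the data (Spearman's rho -0.763, against -0.344 to -0.278 in the comparisons with vehicle). The check therefore covers only the removal of a smooth trend, which the correction is built to remove.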

Results

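RNA sequencing was used to measure gene expression in neurospheres of ReNcell VM, an immortalised human neural progenitor line, that differentiated for 6 days in the presence of phthalate esters. The 10 libraries fell into 5 groups of 2: a vehicle control (0.1% DMSO), DEP (diethyl phthalate), DProP, DPP and a mixture (Mix), each treatment at 100 µM. The labels do not spell out DProP or DPP and do not give the make-up of Mix. DProP is the usual short form of di-n-propyl phthalate, whereas DPP is used for more than 1 phthalate, so no structure is given for it. Each library pooled the RNA of 6 neurospheres, and the labels do not say whether the libraries of a group came from separate cultures, so the p values measure the spread between these libraries. The study addresses developmental neurotoxicity, in terms of progenitor proliferation and migration, the formation of neurons and oligodendrocytes, and neurite growth. Vehicle libraries held 69697714 and 60695361 counts, DEP libraries 69967598 and 69467394, DProP libraries 57222381 and 70845673, DPP libraries 70127862 and 64635092 and Mix libraries 72973100 and 61682236. At this depth 19465 genes entered the tests, and the common biological coefficient of variation was 9.40%. The median 95% interval of a log2 fold change reached 0.26 to each side.

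The vehicle libraries stood apart from all 8 treated libraries in their RNA classes. The libraries were made by exome capture, and which noncoding and mitochondrial transcripts the kit targets is not given in the sources used here. For such transcripts, here and below, a difference in capture cannot be told apart from a difference in expression. Mitochondrially encoded transcripts made up 0.0299% ± 0.00623 of counts in vehicle (SD, n = 2 libraries per group) and 0.0844% ± 0.00276, 0.0909% ± 0.00111, 0.0970% ± 0.0145 and 0.0982% ± 0.00189 in DEP, DProP, DPP and Mix. MALAT1, an abundant nuclear long non-coding RNA (lncRNA), took 1.1% ± 0.215 of counts in vehicle and 0.378% ± 0.0228, 0.369% ± 0.0131, 0.366% ± 0.0333 and 0.346% ± 0.00303 in the same treatments. The median of the 1875 tested lncRNA genes nonetheless lay above vehicle, with log2 fold changes of 0.88, 0.88, 0.84 and 0.65 in DEP, DProP, DPP and Mix. For the 14905 protein-coding genes that median was -0.04, -0.04, -0.04 and -0.01. Between 22905 and 23646 genes had a count in a treated library, against 21603 and 21500 in the vehicle libraries. Across protein-coding genes, which are not independent replicates, the log2 fold change against vehicle fell with GC content (Spearman's rho from -0.344 to -0.278 in the 4 comparisons), whereas rho lay from -0.0397 to 0.132 in the 6 comparisons between treatments. Scaling by library size in place of TMM moved the median of all genes against vehicle by 0.16, 0.18, 0.16 and 0.14 (log2) in DEP, DProP, DPP and Mix, so fold changes against vehicle are relative to the TMM scale. The labels give no culture or library batch, and a batch that coincided with the vehicle group cannot be told apart from treatment in the 4 comparisons with vehicle.

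**Figure D1:**
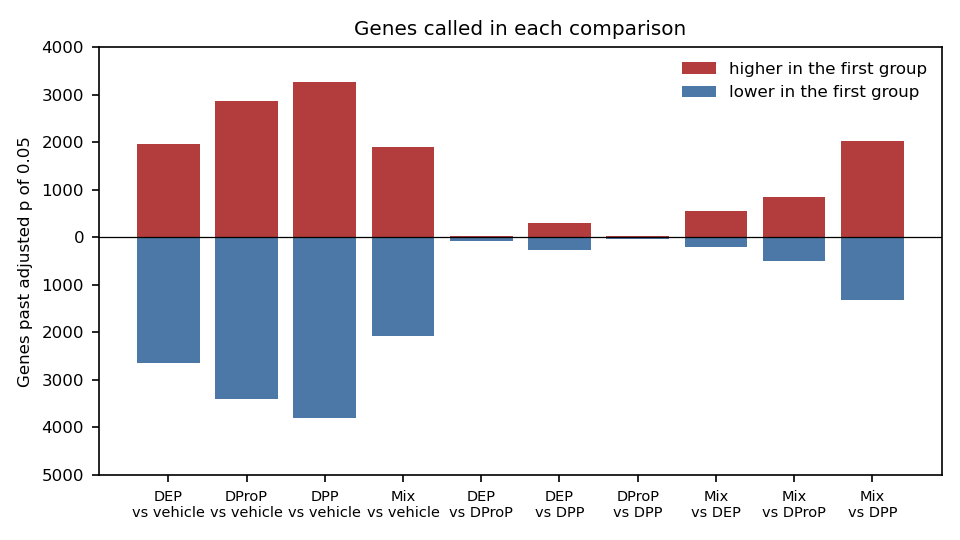
Bars give the number of genes past an adjusted p of 0.05 (vertical axis) in each of the 10 comparisons (horizontal axis), with genes higher in the first-named group above 0 and genes lower in it below 0. Counts against vehicle ran from 3970 for Mix to 7049 for DPP, and those among the 3 single compounds from 51 for DProP against DPP to 571 for DEP against DPP.

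DEP against vehicle asks which transcripts this phthalate altered. Lists of progenitor and astrocyte markers were lower after DEP, and the list of neuronal markers leaned lower (adjusted p = 0.168 with an estimated correlation). VIM, an intermediate filament of progenitors and glia, fell from 2690.1 ± 17.1 to 1395 ± 58.6 CPM (counts scaled to the library total by TMM, mean ± SD, n = 2 libraries per group), a log2 fold change of -0.95 ± 0.07 (SE) with an adjusted p of 1.32e-05 from edgeR's quasi-likelihood test. The proneural transcription factor gene NEUROD1 (log2 fold change -1.14 ± 0.16, adjusted p = 0.000553) and the neuronal intermediate filament gene INA (-0.65 ± 0.08, adjusted p = 0.000329) also fell. GFAP, the filament of astrocytes, fell by 0.80 on the log2 scale (SE 0.08, adjusted p = 6.22e-05). In both DEP libraries each of these genes lay below both vehicle libraries. Every gene given with a log2 fold change below likewise has both libraries of a group beyond both of the other in its own comparison.

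Of 21 measured progenitor markers 16 fell and none rose, or 17 adjusted over the list alone (median -0.40, camera adjusted p = 5.76e-20, adjusted p = 0.00949 with an estimated correlation). Of 21 astrocyte markers 13 fell, the same number adjusted over the list alone, among them CLU (-0.90 ± 0.06), a secreted chaperone, and SLC1A3 (-0.79 ± 0.08), a glutamate transporter (median -0.44, camera adjusted p = 2.76e-12, adjusted p = 0.0214 with an estimated correlation). Of 29 neuronal markers 18 fell, or 20 adjusted over the list alone (median -0.47, camera adjusted p = 8.62e-10, adjusted p = 0.168 with an estimated correlation). Genes of migration, adhesion and extracellular matrix fell in 24 of 47 cases, or 26 with 1 higher adjusted over the list alone (median -0.28, camera adjusted p = 1.31e-13, adjusted p = 0.00949 with an estimated correlation). They included CCN2 (-1.39 ± 0.10) and CCN1 (-1.37 ± 0.12), matricellular targets of YAP, and the collagen-binding protein gene SPARC (-0.71 ± 0.05). Smooth muscle genes of the mesenchymal list gave some of the largest decreases: MYL9, a myosin light chain gene (gene 10398, chromosome 20, 36541519 to 36551447 of GRCh38), fell from 23.8 ± 2.47 to 3.13 ± 0.298 CPM, and TAGLN (-2.11 ± 0.13) and ACTA2 (-1.52 ± 0.13) fell with it. In that list 7 of 17 genes fell and 1 rose, with the same counts adjusted over the list alone (median -0.34, camera adjusted p = 0.000667, adjusted p = 0.0696 with an estimated correlation). Among 18 Notch genes 9 fell, or 10 adjusted over the list alone, including NOTCH1 (-0.58 ± 0.06) and the ligand gene DLL3 (-1.49 ± 0.20) (median -0.35, camera adjusted p = 4.17e-05, adjusted p = 0.188 with an estimated correlation).

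All 13 tested mitochondrially encoded transcripts rose, for example ND4 of complex I (1.35 ± 0.11), with the same count adjusted over the list alone (median 1.46, camera adjusted p = 3.69e-37, adjusted p = 0.0696 with an estimated correlation). Of 75 cytosolic ribosomal protein genes 48 fell and 1 rose, or 51 and 2 adjusted over the list alone (median -0.38, camera adjusted p = 4.36e-30, adjusted p = 0.168 with an estimated correlation). RPL38 stood at -1.03 ± 0.06. The mitochondrial transcripts are 1 of the RNA classes that set the vehicle libraries apart. Metallothionein genes MT1X (1.08 ± 0.12) and MT2A (1.01 ± 0.18), which encode metal-binding proteins of similar sequence, were among 4 of 9 members of the metallothionein list that rose, against 1 that fell, with the same counts adjusted over the list alone (median 1.01, camera adjusted p = 0.0162, adjusted p = 0.166 with an estimated correlation). The DEP libraries differed here: the list's mean centred log2 CPM was -0.0133 in DEP 1 and 0.504 in DEP 2, against -0.498 and -0.268 in vehicle. In the neurite and axon guidance list 13 of 44 genes fell and 4 rose, or 14 and 5 adjusted over the list alone (median -0.12, or 0.0355 with library size alone, camera adjusted p = 0.00454, adjusted p = 0.0703 with an estimated correlation). SLIT3 (-1.64 ± 0.17) and SLIT1 (-0.70 ± 0.10), which encode axon guidance cues, were among those that fell. The oligodendrocyte list was not called (camera adjusted p = 0.102, median -0.45, mean 0.07): 3 of its 14 genes fell, the same number adjusted over the list alone. The cell cycle list was not called either (camera adjusted p = 0.904), with a median of 0.02 over 34 genes.

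The list calls of 4 further groups ended under some alternatives. Immediate early genes, the rapid transcriptional response to stimuli, rose in 9 and fell in 5 of 32 cases, or 10 and 6 adjusted over the list alone, with JUNB at 1.07 ± 0.14 and NR4A1 at -0.87 ± 0.14 (median 0.22, camera adjusted p = 0.0230, adjusted p = 0.579 with an estimated correlation). Their call ended without vehicle 1 (adjusted p = 0.116) or DEP 1 (adjusted p = 0.0664). Heat shock genes fell in 7 and rose in 2 of 18 cases, or 8 and 2 adjusted over the list alone (median -0.15, or 0.0077 with library size alone, camera adjusted p = 0.0195, adjusted p = 0.318 with an estimated correlation). HSPA8 stood at -0.57 ± 0.06. Endoplasmic reticulum chaperone genes fell in 7 of 28 cases and rose in 1, with the same counts adjusted over the list alone (median -0.11, or 0.0515 with library size alone, camera adjusted p = 0.0352, adjusted p = 0.397 with an estimated correlation). CALR, a calcium-binding chaperone gene, stood at -0.54 ± 0.06. PPAR targets fell in 9 of 40 cases and rose in 1, or 12 and 1 adjusted over the list alone (median -0.08, or 0.0721 with library size alone, camera adjusted p = 0.0230, adjusted p = 0.265 with an estimated correlation). The lipid droplet gene PLIN2 stood at -0.65 ± 0.12. The PPAR list was called in DEP alone, but its medians in the 4 treatments ran from -0.149 to -0.0812, so the fall was not particular to DEP. These last 3 calls ended without vehicle 2 (adjusted p = 0.0703, 0.0703 and 0.0776) and with the stricter expression filter (adjusted p = 0.0952, 0.175 and 0.0880). The chaperone call also ended without DEP 1 (adjusted p = 0.0562).

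In total 1964 genes rose and 2637 fell after DEP on the TMM scale, whereas with library size alone 4794 rose and 1259 fell. The largest increases of the naming rule included MAFA, a transcription factor gene (2.38 ± 0.25, adjusted p = 0.000102), and IPW (2.54 ± 0.27), an lncRNA of the imprinted Prader-Willi region. The largest decreases included APLNR, the apelin receptor gene (-2.45 ± 0.35, adjusted p = 0.000674), the junctophilin gene JPH2 (-2.38 ± 0.29) and the potassium channel subunit gene KCNE5 (-2.19 ± 0.24). FLG, which encodes filaggrin, stood at -2.49 ± 0.40, and its call ended without DEP 2 (adjusted p = 0.0562) and in a fit of the 2 groups alone (adjusted p = 0.0710). The count of 4601 became 2075 without DEP 1 and 2248 without DEP 2, and with a 2-fold minimum it was 995.

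DProP against vehicle asks the same of the next compound. Progenitor and astrocyte lists were lower. The neuronal list leaned lower and the cholesterol synthesis list leaned higher (adjusted p = 0.0760 and 0.0760 with an estimated correlation). ELAVL3, a neuronal RNA-binding protein gene, fell from 73 ± 1.67 to 22.7 ± 1.12 CPM (log2 fold change -1.69 ± 0.13, adjusted p = 1.28e-05). INSIG1, a sterol-responsive regulator of the synthesis pathway, rose from 84.2 ± 2.71 to 144 ± 5.48 CPM (0.78 ± 0.06, adjusted p = 5.55e-06), and the lanosterol synthase gene LSS rose by 0.53 ± 0.05 (adjusted p = 3.94e-05). ABCG1 (-2.12 ± 0.27, adjusted p = 0.000282) and APOE (-1.85 ± 0.18), both LXR targets that act in cholesterol export, fell. Both DProP libraries lay beyond both vehicle libraries for each of these genes.

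In the cholesterol synthesis list 16 of 25 genes rose and 1 fell, or 17 and 1 adjusted over the list alone (median 0.43, camera adjusted p = 2.89e-13, adjusted p = 0.0760 with an estimated correlation). In the list of cholesterol efflux and LXR targets 7 of 11 genes fell, the same number adjusted over the list alone (median -0.30, camera adjusted p = 3.66e-05, adjusted p = 0.0645 with an estimated correlation). Of 29 neuronal markers 21 fell and 1 rose, or 21 and 2 adjusted over the list alone (median -0.95, camera adjusted p = 7.09e-16, adjusted p = 0.0760 with an estimated correlation). Progenitor markers fell in 18 of 21 cases, the same number adjusted over the list alone, including SOX2 (-0.70 ± 0.06) and NES (-0.60 ± 0.06), which encode a stem cell transcription factor and nestin (median -0.48, camera adjusted p = 3.36e-16, adjusted p = 0.0257 with an estimated correlation). Astrocyte markers fell in 15 of 21 cases and rose in 2, or 16 and 2 adjusted over the list alone (median -0.50, camera adjusted p = 5.92e-12, adjusted p = 0.0257 with an estimated correlation). For migration, adhesion and matrix, 23 of 47 genes fell and 5 rose, or 25 and 5 adjusted over the list alone, with the brain proteoglycan genes BCAN (-1.11 ± 0.09) and CSPG5 (-0.94 ± 0.07) among those that fell (median -0.25, camera adjusted p = 4.86e-07, adjusted p = 0.0257 with an estimated correlation).

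Cilium genes fell in 15 of 30 cases and rose in 1, or 16 and 1 adjusted over the list alone (median -0.54, camera adjusted p = 1.97e-06, adjusted p = 0.296 with an estimated correlation). CFAP45 of motile cilia stood at -1.82 ± 0.16. Cell cycle genes rose in 17 of 34 cases, or 22 adjusted over the list alone, including the thymidylate synthase gene TYMS (0.88 ± 0.16) (median 0.89, camera adjusted p = 2.24e-05, adjusted p = 0.496 with an estimated correlation). The libraries differed here: the list's mean centred log2 CPM was 0.0173 in DProP 1 and 0.984 in DProP 2, against -0.184 and -0.224 in vehicle. Notch genes fell in 10 of 18 cases and rose in 1, or 11 and 3 adjusted over the list alone, with HES4 at -1.08 ± 0.13 (median -0.43, camera adjusted p = 0.000173, adjusted p = 0.197 with an estimated correlation), and this call ended with the GC and length correction (adjusted p = 0.0511). Immediate early genes rose in 15 and fell in 6 of 32 cases, or 17 and 6 adjusted over the list alone (median 0.35, camera adjusted p = 0.000819, adjusted p = 0.463 with an estimated correlation). EGR2 stood at 1.21 ± 0.16. Mesenchymal and smooth muscle genes fell in 7 and rose in 2 of 17 cases, with the same counts adjusted over the list alone (median -0.38, camera adjusted p = 0.00379, adjusted p = 0.0781 with an estimated correlation). MYL9 stood at -2.95 ± 0.28. Among thyroid hormone, glucocorticoid and retinoid targets 9 of 20 fell and 1, the kinase gene SGK1 (1.76 ± 0.20), rose, with the same counts adjusted over the list alone (median -0.42, camera adjusted p = 0.00815, adjusted p = 0.189 with an estimated correlation).

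Mitochondrially encoded transcripts rose in all 13 cases, the same number adjusted over the list alone (median 1.53, camera adjusted p = 2.07e-31, adjusted p = 0.0760 with an estimated correlation), and ribosomal protein genes fell in 61 and rose in 1 of 75, or 63 and 2 adjusted over the list alone (median -0.54, camera adjusted p = 3.21e-49, adjusted p = 0.0760 with an estimated correlation). Nuclear genes of oxidative phosphorylation fell in 16 and rose in 0 of 46 cases, or 17 and 0 adjusted over the list alone (median -0.12, or 0.0564 with library size alone, camera adjusted p = 0.000414, adjusted p = 0.463 with an estimated correlation). UQCRB of complex III stood at -0.80 ± 0.06. Heat shock genes fell in 8 and rose in 1 of 18 cases, or 8 and 2 adjusted over the list alone (median -0.18, or -0.00701 with library size alone, camera adjusted p = 0.00240, adjusted p = 0.192 with an estimated correlation). The small heat shock protein gene HSPB1 stood at -0.85 ± 0.08. Neurite and axon guidance genes fell in 16 and rose in 5 of 44 cases, or 18 and 6 adjusted over the list alone (median -0.10, or 0.08 with library size alone, camera adjusted p = 0.0200, adjusted p = 0.0979 with an estimated correlation). DPYSL2 stood at -0.72 ± 0.06. That call ended with the stricter filter (adjusted p = 0.0974) and the GC and length correction (adjusted p = 0.0593).

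In all, 2864 genes rose and 3402 fell on the TMM scale, whereas with library size alone 5850 rose and 1699 fell. The largest increases included DKK1, a secreted Wnt inhibitor gene (2.42 ± 0.30, adjusted p = 0.000147), and ID1, a BMP-responsive inhibitor of differentiation (2.40 ± 0.28). The largest decreases included MYL9, the cilium gene CFAP100 (-2.58 ± 0.24), the cardiac actin gene ACTC1 (-2.29 ± 0.41) and HSD11B2 (-2.29 ± 0.27), which encodes an enzyme that inactivates cortisol. The oligodendrocyte list was not called (camera adjusted p = 0.198). The count of 6266 became 3976 without DProP 2, and it was 1385 with a 2-fold minimum.

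DPP against vehicle gave the largest count of the 4, with 3256 genes higher and 3793 lower on the TMM scale, whereas with library size alone 5820 rose and 2200 fell. The neuronal list leaned lower and the immediate early, hypoxia, NFE2L2 and ATF4 lists leaned higher, with both directions among their members. None of these calls held with an estimated correlation (adjusted p = 0.0752, 0.157, 0.219, 0.358 and 0.301 with an estimated correlation). NEUROD1 fell from 13.0 ± 1.64 to 2.85 ± 0.348 CPM (log2 fold change -2.18 ± 0.17, adjusted p = 4.21e-06), and INA fell with it (-1.37 ± 0.08, adjusted p = 1.78e-06). GDF15, a stress-induced cytokine gene (gene 9518, chromosome 19, 18386158 to 18389176 of GRCh38), rose from 1.77 ± 0.440 to 19.0 ± 4.3 CPM (3.41 ± 0.23, adjusted p = 3.16e-06). EGR2, an immediate early transcription factor gene, rose by 2.42 ± 0.16 (adjusted p = 2.08e-06) and ADM, the hypoxia-inducible adrenomedullin gene, by 2.33 ± 0.16 (adjusted p = 3.16e-06). Both DPP libraries lay beyond both vehicle libraries for all of these.

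Of 29 neuronal markers 21 fell and 2 rose, or 21 and 3 adjusted over the list alone (median -1.09, camera adjusted p = 6.9e-20, adjusted p = 0.0752 with an estimated correlation). Progenitor markers fell in 16 and rose in 2 of 21 cases, or 17 and 2 adjusted over the list alone (median -0.48, camera adjusted p = 3.26e-12, adjusted p = 0.0400 with an estimated correlation). ID4, a differentiation inhibitor, stood at -0.99 ± 0.07. Astrocyte markers fell in 16 and rose in 2 of 21 cases, the same adjusted over the list alone (median -0.48, camera adjusted p = 5.61e-09, adjusted p = 0.0400 with an estimated correlation). The progenitor and astrocyte lists had identical medians here, also with library size alone (-0.326). They thus have a gene in common and are not fully separate results in any comparison. Genes of migration, adhesion and matrix fell in 24 and rose in 7 of 47 cases, the same adjusted over the list alone (median -0.29, camera adjusted p = 2.05e-06, adjusted p = 0.0400 with an estimated correlation). RELN, which encodes the migration cue reelin, stood at -1.62 ± 0.12. Cilium genes fell in 21 of 30 cases, or 21 and 2 higher adjusted over the list alone (median -0.66, camera adjusted p = 3.93e-09, adjusted p = 0.157 with an estimated correlation). SPAG6 of the axoneme stood at -2.64 ± 0.28. Synapse and ion channel genes fell in 17 and rose in 6 of 44 cases, the same adjusted over the list alone (median -0.21, or -0.0470 with library size alone, camera adjusted p = 0.0213, adjusted p = 0.147 with an estimated correlation). The vesicle release gene CPLX2 stood at -1.93 ± 0.17. The synapse call ended with the stricter filter (adjusted p = 0.124) and the GC and length correction (adjusted p = 0.139). Notch genes fell in 10 and rose in 2 of 18 cases, or 11 and 2 adjusted over the list alone (median -0.42, camera adjusted p = 0.000148, adjusted p = 0.157 with an estimated correlation). DLL3 stood at -2.12 ± 0.21. The neurite list missed the threshold (camera adjusted p = 0.0512), and so did the oligodendrocyte list (camera adjusted p = 0.0921).

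Immediate early genes rose in 20 and fell in 5 of 32 cases, or 20 and 6 adjusted over the list alone, with the AP-1 gene FOSL1 at 2.44 ± 0.19 and DUSP4, a MAP kinase phosphatase gene, at 1.90 ± 0.18 (median 0.60, camera adjusted p = 3.65e-10, adjusted p = 0.157 with an estimated correlation). Hypoxia and glycolysis genes rose in 18 and fell in 6 of 35 cases, or 20 and 7 adjusted over the list alone (median 0.27, camera adjusted p = 0.000120, adjusted p = 0.219 with an estimated correlation). The hexokinase gene HK2 stood at 1.43 ± 0.10. Among p53 targets and apoptosis genes 17 of 32 rose and 2 fell, the same adjusted over the list alone (median 0.23, camera adjusted p = 0.000120, adjusted p = 0.157 with an estimated correlation). The cyclin-dependent kinase inhibitor gene CDKN1A stood at 0.78 ± 0.06. NFE2L2 antioxidant genes rose in 14 and fell in 6 of 27 cases, the same adjusted over the list alone (median 0.21, camera adjusted p = 0.00327, adjusted p = 0.358 with an estimated correlation). The sulfiredoxin gene SRXN1 stood at 1.18 ± 0.09. ATF4 targets of the integrated stress response rose in 16 and fell in 8 of 43 cases, or 17 and 9 adjusted over the list alone (median 0.13, camera adjusted p = 0.00541, adjusted p = 0.301 with an estimated correlation). The asparagine synthetase gene ASNS stood at 1.03 ± 0.09. Metallothionein list genes rose in 5 and fell in 1 of 9 cases, the same adjusted over the list alone, with MT1X at 1.29 ± 0.12 and the brain form MT3 at -1.87 ± 0.36 (median 0.50, camera adjusted p = 0.0155, adjusted p = 0.147 with an estimated correlation). Cell cycle genes rose in 3 of 34 cases, the same adjusted over the list alone (median 0.43, camera adjusted p = 0.0133, adjusted p = 0.765 with an estimated correlation). PCNA stood at 0.40 ± 0.09.

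Cholesterol synthesis genes rose in 13 and fell in 3 of 25 cases, or 15 and 3 adjusted over the list alone (median 0.23, camera adjusted p = 0.000347, adjusted p = 0.234 with an estimated correlation). INSIG1 stood at 0.55 ± 0.06. Efflux and LXR targets fell in 6 of 11 cases, the same adjusted over the list alone (median -0.46, camera adjusted p = 0.00327, adjusted p = 0.12 with an estimated correlation). ABCG1 stood at -2.39 ± 0.27. Thyroid hormone, glucocorticoid and retinoid targets fell in 10 and rose in 1 of 20 cases, or 11 and 1 adjusted over the list alone, with the retinoic acid binding protein gene CRABP1 at -2.18 ± 0.21 and SGK1 at 2.75 ± 0.20 (median -0.48, camera adjusted p = 0.00431, adjusted p = 0.147 with an estimated correlation). Mesenchymal genes fell in 5 and rose in 5 of 17 cases, the same adjusted over the list alone, with TAGLN at -2.57 ± 0.13 (median -0.21, camera adjusted p = 0.0155, adjusted p = 0.147 with an estimated correlation), and this call ended without DPP 1 (adjusted p = 0.0535). With library size alone the mesenchymal median was -0.0514. All 13 mitochondrially encoded transcripts rose, also adjusted over the list alone (median 1.69, camera adjusted p = 1.53e-30, adjusted p = 0.101 with an estimated correlation), and 57 of 75 ribosomal protein genes fell while 2 rose, or 60 and 2 adjusted over the list alone (median -0.51, camera adjusted p = 7.43e-34, adjusted p = 0.147 with an estimated correlation).

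The largest increases after DPP included IL11, a cytokine gene (6.08 ± 0.88, adjusted p = 0.00145), whose vehicle mean was 0.0861 ± 0.122 CPM, RGS4, a regulator of G protein signalling (3.0 ± 0.18), and DKK1 (3.0 ± 0.30). The largest decreases included MYL9 (-3.94 ± 0.30), SAMD11 (-3.75 ± 0.39), CFAP100 (-3.25 ± 0.25), CDH5, the gene of an endothelial cadherin (-2.85 ± 0.57), and SEMA3F, an axon repellent gene (-2.83 ± 0.40). The count of 7049 became 4343 without DPP 2, and with a 2-fold minimum it was 1733.

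Mix against vehicle asks what a combined exposure altered. Lists of progenitor and matrix genes were lower, while NEUROD1 averaged 13.1 ± 0.601 CPM in Mix and 13.0 ± 1.64 in vehicle. VIM fell to 1381 ± 120.1 CPM (-0.96 ± 0.07, adjusted p = 8.59e-06), and FABP7, a fatty acid binding protein gene of radial glia, fell by 1.45 on the log2 scale (SE 0.12, adjusted p = 3.04e-05). FTH1, the ferritin heavy chain gene, fell as well (-1.38 ± 0.10, adjusted p = 9.83e-06). Among neuronal genes the neurofilament gene NEFL (-0.88 ± 0.10, adjusted p = 0.000148) and SOX11 (-0.46 ± 0.08, adjusted p = 0.00210) fell. Both Mix libraries lay below both vehicle libraries for the genes that fell.

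Progenitor markers fell in 13 and rose in 1 of 21 cases, or 15 and 3 adjusted over the list alone (median -0.29, camera adjusted p = 5.84e-12, adjusted p = 0.0317 with an estimated correlation). Genes of migration, adhesion and matrix fell in 19 and rose in 3 of 47 cases, or 22 and 4 adjusted over the list alone (median -0.21, camera adjusted p = 4.55e-08, adjusted p = 0.0317 with an estimated correlation). CCN2 stood at -1.48 ± 0.10. Astrocyte markers fell in 10 and rose in 3 of 21 cases, or 10 and 4 adjusted over the list alone (median -0.26, camera adjusted p = 3.11e-06, adjusted p = 0.0592 with an estimated correlation). The gap junction gene GJA1 stood at -0.56 ± 0.06. Neuronal markers fell in 10 and rose in 3 of 29 cases, or 12 and 4 adjusted over the list alone (median -0.23, or -0.0901 with library size alone, camera adjusted p = 0.00213, adjusted p = 0.473 with an estimated correlation). Cilium genes fell in 14 and rose in 1 of 30 cases, or 16 and 1 adjusted over the list alone (median -0.51, camera adjusted p = 1.33e-07, adjusted p = 0.373 with an estimated correlation). The dynein gene DNAI1 stood at -1.0 ± 0.16. Mesenchymal genes fell in 6 of 17 cases and rose in none, or 6 and 1 adjusted over the list alone (median -0.39, camera adjusted p = 0.000129, adjusted p = 0.0584 with an estimated correlation). ACTA2 stood at -1.60 ± 0.13. Cholesterol synthesis genes rose in 11 and fell in 1 of 25 cases, or 12 and 2 adjusted over the list alone (median 0.12, camera adjusted p = 0.00205, adjusted p = 0.469 with an estimated correlation). INSIG1 stood at 0.48 ± 0.06. Efflux and LXR targets fell in 4 of 11 cases, or 6 adjusted over the list alone, with ABCA1 at -0.51 ± 0.07 (median -0.29, camera adjusted p = 0.0116, adjusted p = 0.163 with an estimated correlation), and this call ended with the GC and length correction (adjusted p = 0.0542).

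NFE2L2 genes fell in 8 and rose in 2 of 27 cases, the same adjusted over the list alone (median -0.11, or 0.00943 with library size alone, camera adjusted p = 0.000795, adjusted p = 0.469 with an estimated correlation). FTL, the ferritin light chain gene, stood at -0.52 ± 0.06. Notch genes fell in 6 and rose in 1 of 18 cases, or 7 and 1 adjusted over the list alone (median -0.13, or 0.00884 with library size alone, camera adjusted p = 0.00696, adjusted p = 0.469 with an estimated correlation), and that call ended with the GC and length correction (adjusted p = 0.561). Nuclear genes of oxidative phosphorylation fell in 12 of 46 cases, or 15 adjusted over the list alone (median -0.12, or 0.0207 with library size alone, camera adjusted p = 9.96e-05, adjusted p = 0.571 with an estimated correlation). UQCRB stood at -0.80 ± 0.06. Heat shock genes fell in 6 of 18 cases, or 7 adjusted over the list alone (median -0.16, or -0.0184 with library size alone, camera adjusted p = 0.000174, adjusted p = 0.163 with an estimated correlation). HSP90AA1 stood at -0.59 ± 0.07. All 13 mitochondrially encoded transcripts rose, also adjusted over the list alone (median 1.63, camera adjusted p = 3.2e-51, adjusted p = 0.0573 with an estimated correlation). Of 75 ribosomal protein genes 59 fell and 1 rose, or 60 and 1 adjusted over the list alone (median -0.52, camera adjusted p = 1.8e-63, adjusted p = 0.0638 with an estimated correlation). The neurite, oligodendrocyte and cell cycle lists were not called (camera adjusted p = 0.365, 0.980 and 0.550).

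After Mix 1891 genes rose and 2079 fell on the TMM scale, whereas with library size alone 4605 rose and 1020 fell. Its largest increases included the lncRNA genes OIP5-AS1 (2.21 ± 0.17, adjusted p = 9.83e-06) and LINC00641 (2.21 ± 0.18). Strand use is not given in the sources used here, so reads of overlapping genes may not have been told apart from theirs. The protein-coding GABRQ, a GABA receptor subunit gene, rose (2.55 ± 0.51, adjusted p = 0.00696), and its call ended without vehicle 2 (adjusted p = 0.0612). The largest decreases included RRAD, a small GTPase gene (-2.39 ± 0.30), SEMA3F (-2.28 ± 0.39), MYL9 (-2.24 ± 0.27) and the tight junction gene CLDN1 (-2.22 ± 0.21). The count of 3970 became 1569 without Mix 1 and 2426 without vehicle 2, and it was 810 with a 2-fold minimum.

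**Figure D2:**
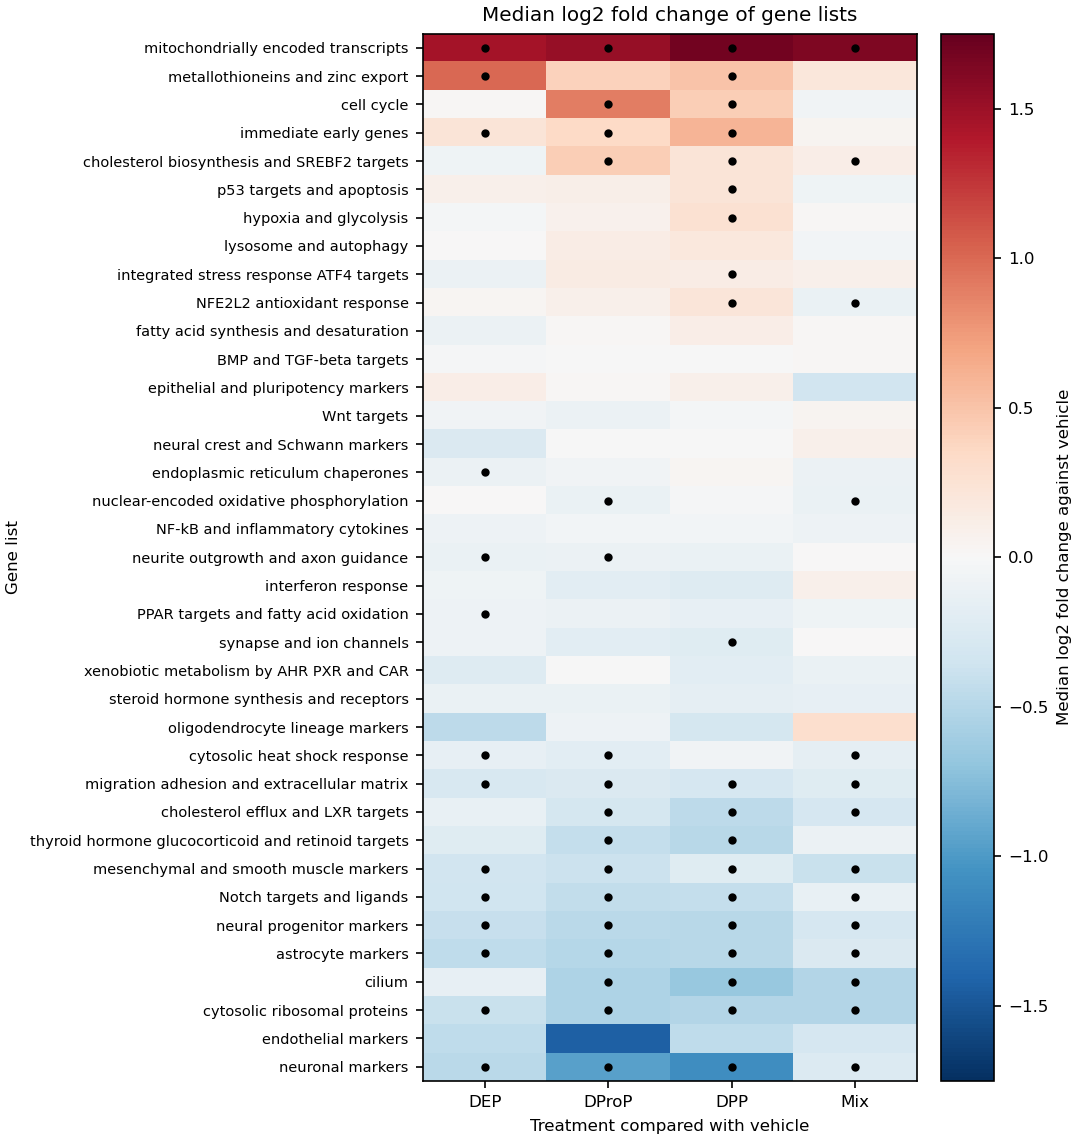
Each cell gives the median log2 fold change of a gene list (vertical axis, 37 lists) against vehicle in each treatment (horizontal axis), on the colour scale at the right, and a dot marks a camera adjusted p under 0.05. On the TMM scale the medians of neuronal markers were -0.47, -0.95, -1.09 and -0.23 in DEP, DProP, DPP and Mix, and those of cholesterol synthesis genes -0.07 (not called, and smaller than the shift of 0.16 between scalings), 0.43, 0.23 and 0.12. With library size alone some other marked medians turn positive, and some come close to 0.

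Genes called in the same direction in all 4 treatments numbered 2191, with 948 higher and 1243 lower. They included 1157 lower and 466 higher protein-coding genes, and 313 higher and 5 lower lncRNA genes. Those with the largest mean change included the smooth muscle gene MYL9, which averaged 23.8 ± 2.47 CPM in vehicle and 3.13 ± 0.298, 3.06 ± 0.633, 1.54 ± 0.568 and 5.04 ± 1.80 CPM in DEP, DProP, DPP and Mix. CFAP100 (-2.03 ± 0.23, -2.58 ± 0.24, -3.25 ± 0.25 and -1.57 ± 0.23) and JPH2 (-2.38 ± 0.29, -2.19 ± 0.29, -2.61 ± 0.30 and -1.95 ± 0.29) fell in each, and MAFA (2.38 ± 0.25, 2.36 ± 0.25, 2.82 ± 0.25 and 2.02 ± 0.25) rose in each. The other 6 were IPW, RNA5S6, TRNL1 and SNORD3A, which rose, and FLG and SEMA3F, which fell; RNA5S6 and TRNL1 belong to RNA families with several copies or look-alike sequences. SEMA3F in DEP lost its call without vehicle 1 (adjusted p = 0.0590) or DEP 1 (adjusted p = 0.0781). FLG lost it without DEP 2 in DEP (adjusted p = 0.0562) and without Mix 1 or Mix 2 in Mix (adjusted p = 0.0819 and 0.0535). In a fit of the 2 groups alone it lost it in DEP and DProP (adjusted p = 0.0710 and 0.0957). Of the 37 lists tested, 8 were called in all 4 treatments and 12 in none. The list of xenobiotic metabolism was among the 12 (smallest camera adjusted p = 0.363). With an estimated correlation only the progenitor list and the list of migration, adhesion and matrix were called in all 4. The size of both depended on the scaling. With library size alone the migration medians came closer to 0, at -0.121, -0.0763, -0.131 and -0.0650 in DEP, DProP, DPP and Mix. The progenitor medians were then -0.245, -0.300, -0.326 and -0.147.

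The 4 comparisons share their 2 vehicle libraries, which cannot be split between the comparisons, and shared error in them enters all 4. Across the 19465 genes the log2 fold changes of pairs of treatments correlated with r from 0.729 to 0.835, against 0.502 to 0.516 in 20 simulated sets of unchanged groups that shared the same controls. The covariance was 0.932 to 1.18 against 0.133 to 0.135 in the simulations. For DProP and DPP, 2220 genes rose in both and 2796 fell in both. Independent lists would give 479 and 663, but these lists share their controls. In the 20 simulations the test called 0.675 genes per comparison on average and no gene in all 4. The simulated groups follow the spread that the test assumes and hold no offset of the vehicle libraries. They therefore cannot tell an effect common to the treatments from a batch or GC trend that coincides with vehicle. The count of 2191 became 1436 without vehicle 2, 1350 without DEP 1, 1357 without DEP 2 and 1148 without Mix 1. It was 3322 under scaling by library size (2827 higher and 495 lower), 1436 with the GC and length correction and 557 with a 2-fold minimum.

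The single compounds were compared at the same dose and day, with list tests that were added after the data were seen. The series describes the other linear di-n-alkyl phthalates as differing from DEP in their number of carbon atoms. Between DEP and DProP the lists that held with an estimated correlation were those of cholesterol genes: synthesis genes were lower in DEP. LSS averaged 179 ± 7.71 CPM in DEP and 261 ± 5.02 in DProP (log2 fold change of DEP over DProP -0.54 ± 0.05, adjusted p = 0.00109). ACAT2 (-1.10 ± 0.11, adjusted p = 0.00109), an acetyl-CoA acetyltransferase gene, and the lipase gene PNPLA3 (-1.14 ± 0.10, adjusted p = 0.000895) differed in the same direction. Of 25 synthesis genes 18 were lower in DEP and none higher, or 20 and 1 adjusted over the list alone (median -0.51, camera adjusted p = 1.73e-75, adjusted p = 0.00914 with an estimated correlation). Of 11 efflux and LXR targets 2 were higher in DEP, or 6 adjusted over the list alone (median 0.39, camera adjusted p = 6.54e-11, adjusted p = 0.0169 with an estimated correlation). Both, ABCA1 and APOC1, lost their calls when a library was left out: adjusted p was 0.169 and 0.261 without DEP 1, 0.113 and 0.232 without DEP 2, and 0.104 and 0.163 without DProP 2, and for APOC1 0.0840 without DProP 1. Neuronal markers leaned higher in DEP, with 2 of 29 higher and 1 lower, or 12 and 1 adjusted over the list alone (median 0.25, camera adjusted p = 2.89e-09, adjusted p = 0.231 with an estimated correlation).

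The whole comparison held 26 genes higher and 76 lower in DEP. The count of 102 became 20 without DEP 1, 9 without DEP 2, 267 without DProP 1 and 32 without DProP 2. It was 580 with DESeq2, 489 in a fit of the 2 groups alone, 279 with the stricter filter, 253 with the GC and length correction and 16 with a 2-fold minimum. For 73.2% of genes the 95% interval of the DEP to DProP difference lay within 2-fold in either direction. Of the 16 list calls 2 held with an estimated correlation, those of cholesterol synthesis genes and LXR targets, and fry called 4.

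Between DEP and DPP, single genes of the neuronal, immediate early, hypoxia and stress lists differed, while no list call held with an estimated correlation. INA averaged 65 ± 6.10 CPM in DEP and 39.4 ± 1.88 in DPP (log2 fold change of DEP over DPP 0.72 ± 0.08, adjusted p = 0.00110), and SNAP25, a vesicle fusion gene (1.11 ± 0.14, adjusted p = 0.00156), and STMN4 (1.46 ± 0.16) were also higher in DEP. NEFL went the other way (-1.03 ± 0.10, adjusted p = 0.000800). HMGA2, a chromatin protein gene of growing progenitors, averaged 0.751 ± 0.102 CPM in DEP and 4.78 ± 1.59 in DPP (-2.67 ± 0.26, adjusted p = 0.000800), and GDF15 (-1.84 ± 0.21, adjusted p = 0.00110), EGR2 (-1.44 ± 0.15, adjusted p = 0.000879) and the glucose transporter gene SLC2A1 (-0.67 ± 0.06, adjusted p = 0.000610) were lower in DEP too. Of 29 neuronal markers 14 were higher and 1 lower in DEP, or 19 and 3 adjusted over the list alone (median 0.45, camera adjusted p = 2.2e-19, adjusted p = 0.0656 with an estimated correlation). Cilium genes were higher in DEP in 9 of 30 cases, or 19 adjusted over the list alone (median 0.49, camera adjusted p = 3.21e-19, adjusted p = 0.0830 with an estimated correlation). DNAH11 stood at 1.04 ± 0.12. Immediate early genes were lower in 10 of 32 cases, or 22 adjusted over the list alone (median -0.51, camera adjusted p = 4.91e-20, adjusted p = 0.0787 with an estimated correlation). Lower in DEP were also 12 of 35 hypoxia genes, or 19 adjusted over the list alone, with 3 higher (median -0.23, camera adjusted p = 1.53e-16, adjusted p = 0.0656 with an estimated correlation). Of 27 NFE2L2 genes 9 were lower, or 14 adjusted over the list alone (median -0.21, camera adjusted p = 3.28e-18, adjusted p = 0.0656 with an estimated correlation). HMOX1, the heme oxygenase gene, stood at -0.94 ± 0.11. Of 43 ATF4 targets 11 were lower, or 21 with 1 higher adjusted over the list alone (median -0.21, camera adjusted p = 5.52e-16, adjusted p = 0.0656 with an estimated correlation). Cholesterol synthesis genes were lower in DEP in 12 of 25 cases, or 16 adjusted over the list alone (median -0.28, camera adjusted p = 7.74e-22, adjusted p = 0.0656 with an estimated correlation).

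Over all genes 307 were higher and 264 lower in DEP than in DPP. The count of 571 became 152 without DEP 1, 80 without DEP 2 and 134 without DPP 2, and it was 1110 with DESeq2, 979 in a fit of the 2 groups alone, 1036 with the GC and length correction and 137 with a 2-fold minimum. For 72.5% of genes the 95% interval of the difference lay within 2-fold in either direction. Of the 18 list calls 0 held with an estimated correlation, where 11 lists had an unadjusted p under 0.05, and fry called 12 lists.

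DProP and DPP gave the fewest calls of the 3 pairs with all libraries. HBEGF, an EGF receptor ligand gene, averaged 5.90 ± 0.195 CPM in DProP and 17.3 ± 0.989 in DPP (log2 fold change of DProP over DPP -1.55 ± 0.14, adjusted p = 0.00209). HMGA2 (-2.01 ± 0.25, adjusted p = 0.00897) and EGR2 (-1.21 ± 0.15, adjusted p = 0.00897) were lower in DProP as well. HMGA2 lost its call without DProP 2 (adjusted p = 0.0737) or DPP 2 (adjusted p = 0.0805), or in a fit of the 2 groups alone (adjusted p = 0.0860). EGR2 lost its call without DPP 2 (adjusted p = 0.0834). Immediate early genes were lower in DProP in 4 of 32 cases, or 17 adjusted over the list alone (median -0.25, camera adjusted p = 1.45e-14, adjusted p = 0.159 with an estimated correlation). NFE2L2 genes were lower in 4 of 27, or 12 with 1 higher adjusted over the list alone (median -0.19, camera adjusted p = 4.32e-13, adjusted p = 0.159 with an estimated correlation). Cholesterol synthesis genes were higher in DProP in 1 of 25 cases, or 14 adjusted over the list alone (median 0.19, camera adjusted p = 1.16e-12, adjusted p = 0.159 with an estimated correlation). The direction of the cell cycle list turned on DProP 2: it was higher in DProP (camera adjusted p = 0.00133) and lower without DProP 2 (adjusted p = 1.02e-05), and without DPP 1 its call ended (adjusted p = 0.0607). In total 23 genes were higher and 28 lower in DProP. The count of 51 became 17 without DProP 2, 132 without DPP 1 and 5 without DPP 2. It was 384 with DESeq2, 17 in a fit of the 2 groups alone, 146 with the stricter filter, 203 with the GC and length correction and 23 with a 2-fold minimum. The 95% interval lay within 2-fold for 73.6% of genes, and a difference that missed the threshold does not show that the compounds act alike. Of the 13 list calls 0 held with an estimated correlation, where 7 lists had an unadjusted p under 0.05, and fry called 6.

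**Figure D3:**
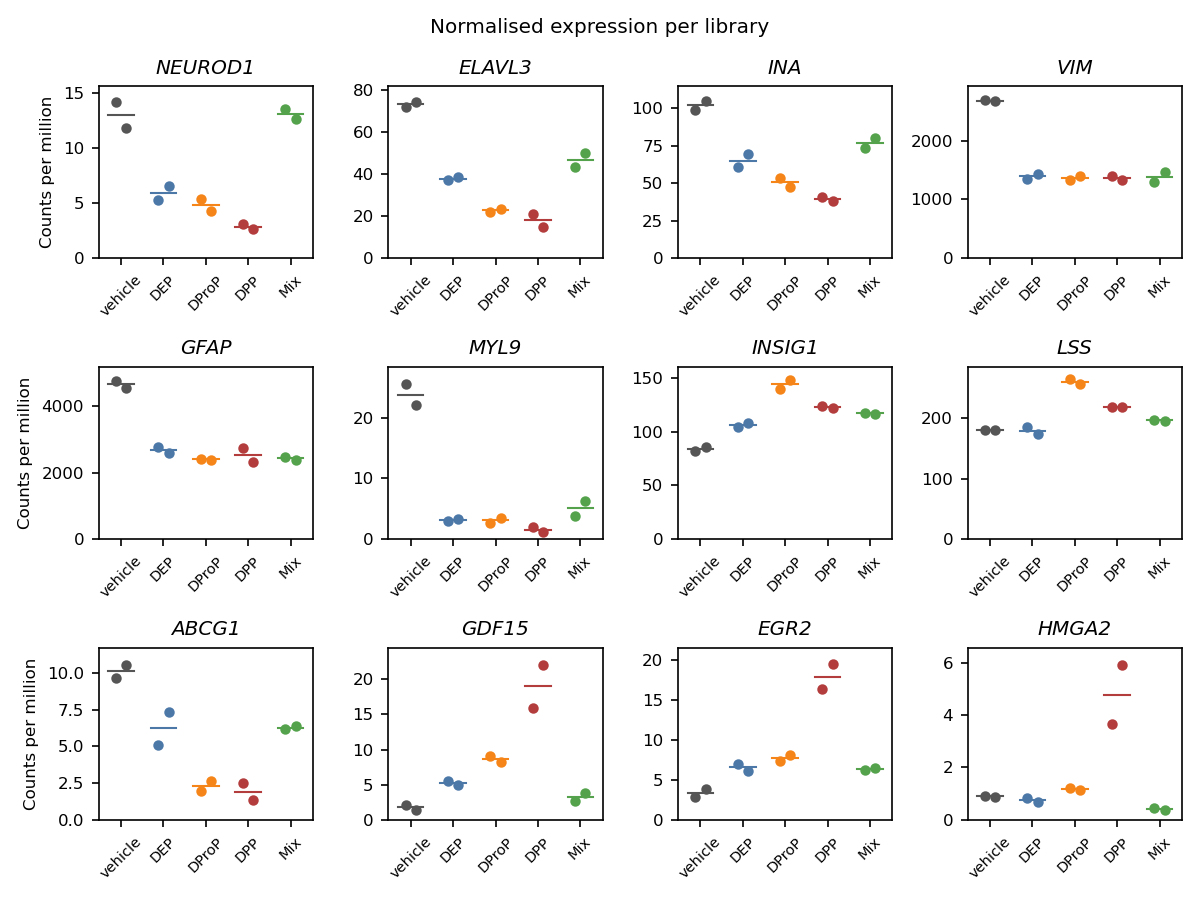
Points give the normalised expression of 12 genes in CPM (vertical axes, from 0) in each library, by group (horizontal axes), and lines give the mean of the 2 libraries of a group. INA averaged 102 ± 4.35 in vehicle, 65 ± 6.10 in DEP, 50.4 ± 3.97 in DProP, 39.4 ± 1.88 in DPP and 76.9 ± 4.75 in Mix (mean ± SD, n = 2).

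Mix was compared with each compound at the same labelled concentration, and whether that is the total of Mix or the amount of each part is not given in the sources used here. The neuronal list leaned higher in Mix against all 3, a call that was lost with an estimated correlation (adjusted p = 0.132, 0.147 and 0.330 with an estimated correlation against DPP, DProP and DEP), while NEFL was lower against all 3. Against DEP its call ended without DEP 1 or Mix 1 (adjusted p = 0.101 and 0.0658). Against DPP, NEUROD1 (2.19 ± 0.17, adjusted p = 2.04e-05) and INA (0.96 ± 0.08, adjusted p = 3.8e-05) were higher in Mix, and HMGA2 (-3.51 ± 0.28, adjusted p = 2.18e-05), GDF15 (-2.57 ± 0.21, adjusted p = 3.8e-05) and DUSP4 (-2.0 ± 0.18) were lower. Of 29 neuronal markers 21 were higher in Mix than in DPP and 1, NEFL (-1.70 ± 0.10), lower, or 22 and 1 adjusted over the list alone (median 0.95, camera adjusted p = 2.36e-20, adjusted p = 0.132 with an estimated correlation). NFE2L2 genes were lower in 15 and higher in 1 of 27 cases, or 18 and 2 adjusted over the list alone (median -0.39, camera adjusted p = 6.32e-16, adjusted p = 0.132 with an estimated correlation). SRXN1 stood at -0.95 ± 0.09. Immediate early genes were lower in 19 and higher in 1 of 32, or 23 and 2 adjusted over the list alone (median -0.57, camera adjusted p = 2.98e-14, adjusted p = 0.152 with an estimated correlation). Among p53 targets 19 of 32 were lower and 1 higher, or 25 and 1 adjusted over the list alone (median -0.32, camera adjusted p = 3.19e-11, adjusted p = 0.132 with an estimated correlation). CDKN1A stood at -0.63 ± 0.06. The largest differences included SAMD11 (3.02 ± 0.39), BPIFB2 (2.93 ± 0.30) and the complement inhibitor gene SERPING1 (2.36 ± 0.22), all higher in Mix. In all 2032 genes were higher and 1327 lower in Mix than in DPP. The count of 3359 became 1498 without DPP 2, 1862 without Mix 1 and 1916 without Mix 2, and with a 2-fold minimum it was 576. Of the 19 list calls 0 held with an estimated correlation, where 9 lists had an unadjusted p under 0.05, and fry called 20.

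Against DProP, neuronal markers were higher in Mix in 18 of 29 cases and lower in 1, or 22 and 1 adjusted over the list alone, with ELAVL3 at 1.04 ± 0.13 and NEFL at -1.24 ± 0.10 (median 0.57, camera adjusted p = 1.93e-18, adjusted p = 0.147 with an estimated correlation). The glial transcription factor gene NFIA was higher (0.67 ± 0.07, adjusted p = 0.000616), and so was CPT1C, a neuronal carnitine palmitoyltransferase gene (0.83 ± 0.07, adjusted p = 0.000236). Cell cycle genes were lower in 10 of 34 cases, or 26 adjusted over the list alone (median -0.93, camera adjusted p = 2.95e-16, adjusted p = 0.338 with an estimated correlation), a list whose DProP level rests largely on DProP 2. The largest decreases included TK1 (-2.48 ± 0.34, adjusted p = 0.00174), a thymidine kinase gene, and PKMYT1 (-2.32 ± 0.30, adjusted p = 0.00123), which encodes a CDK1-inhibiting kinase. Cholesterol synthesis genes were lower in Mix in 12 of 25 cases, or 15 adjusted over the list alone (median -0.25, camera adjusted p = 1.29e-13, adjusted p = 0.147 with an estimated correlation). LSS stood at -0.41 ± 0.05. Astrocyte markers were higher in 9 and lower in 2 of 21, or 11 and 4 adjusted over the list alone (median 0.25, camera adjusted p = 8.44e-06, adjusted p = 0.147 with an estimated correlation). HEPACAM stood at 1.12 ± 0.15. In all 849 genes were higher and 493 lower. The count of 1342 became 774 without DProP 1, 542 without DProP 2, 382 without Mix 1 and 772 without Mix 2, and with a 2-fold minimum it was 245. Of the 18 list calls 0 held with an estimated correlation, where 9 lists had an unadjusted p under 0.05, and fry called 12.

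Against DEP, BPIFB2 (2.68 ± 0.29, adjusted p = 0.00103) and the lipoprotein receptor gene VLDLR (0.60 ± 0.07, adjusted p = 0.00145) were higher in Mix. NEUROD1 (1.15 ± 0.16, adjusted p = 0.00330) and APLNR (2.99 ± 0.35, adjusted p = 0.00132) were higher too, and their calls ended without DEP 1 (adjusted p = 0.0885 and 0.0570). Cholesterol synthesis genes were higher in Mix in 8 of 25 cases, or 19 with 1 lower adjusted over the list alone (median 0.21, camera adjusted p = 1.53e-11, adjusted p = 0.170 with an estimated correlation). NEFL was lower (-0.67 ± 0.10, adjusted p = 0.00574), a call that ended without DEP 1 (adjusted p = 0.101) or Mix 1 (adjusted p = 0.0658). Neuronal markers were higher in 3 and lower in 1 of 29 cases, or 8 and 1 adjusted over the list alone (median 0.24, camera adjusted p = 8.12e-06, adjusted p = 0.330 with an estimated correlation). Among p53 targets 4 of 32 were lower, or 10 adjusted over the list alone (median -0.14, camera adjusted p = 3.3e-06, adjusted p = 0.183 with an estimated correlation). In all 554 genes were higher and 198 lower, whereas with the GC and length correction 686 were higher and 533 lower. The count of 752 became 33 without DEP 1, 85 without DEP 2, 125 without Mix 1 and 414 without Mix 2. It was 1361 with DESeq2, 1602 in a fit of the 2 groups alone, 1219 with the GC and length correction and 99 with a 2-fold minimum. Of the 18 list calls 0 held with an estimated correlation, where 7 lists had an unadjusted p under 0.05, and fry called 10.

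Lists of other cell types also leaned higher in Mix than in the single compounds, and none of these calls held with an estimated correlation. For 14 oligodendrocyte markers, 2 were higher against DEP, 1 against DProP and 3 against DPP, with none lower, or 2, 3 and 4 adjusted over the list alone. Their medians were 0.52, 0.40 and 0.54 (camera adjusted p = 0.00825, 0.0331 and 0.0251, adjusted p = 0.250, 0.298 and 0.251 with an estimated correlation). All 3 calls ended without Mix 1 (adjusted p = 0.0560, 0.106 and 0.0901) or Mix 2 (adjusted p = 0.0582, 0.100 and 0.0827). The call against DProP also ended without DProP 1 (adjusted p = 0.373), and that against DPP without DPP 2 (adjusted p = 0.137). With the GC and length correction the oligodendrocyte calls against DProP and DPP ended too (camera adjusted p = 0.0644 and 0.0566). The stricter filter ended the call against DProP (camera adjusted p = 0.0560). Of 21 progenitor markers 6, 7 and 9 were higher and 0, 2 and 3 lower against DEP, DProP and DPP, or 7, 11 and 11 higher and 2, 3 and 4 lower adjusted over the list alone. Their medians were 0.09, 0.16 and 0.18 (camera adjusted p = 0.00105, 0.000343 and 0.0292, adjusted p = 0.170, 0.150 and 0.251 with an estimated correlation). The progenitor call against DPP ended without DPP 1, DPP 2 or Mix 2 (adjusted p = 0.0545, 0.0842 and 0.0827). That progenitor call also ended with the stricter filter (camera adjusted p = 0.0770) and the GC and length correction (camera adjusted p = 0.100). Astrocyte markers were higher in 5 and lower in 0 of 21 cases against DEP, and higher in 9 and lower in 3 against DPP, or 9 and 1, and 11 and 3, adjusted over the list alone. Their medians were 0.10 and 0.32 (camera adjusted p = 0.00105 and 0.00621, adjusted p = 0.170 and 0.182 with an estimated correlation).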

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

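The GC and length correction, the removal of rRNA genes, the fit without both vehicle libraries and the list tests between treatments were chosen after seeing the data. All other alternatives were fixed before the data were examined, and each of them was run. Counts of called genes stayed within 1.5 times the reported value in all 11 results with relative log expression factors, no filter, limma-voom and the replicate block, and with rRNA genes left out. For values outside that range the cause was not tested, except that a fold minimum lowers a count by its construction, through fewer eligible genes. Leaving out a library both lowered and raised counts.

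With a 2-fold minimum the counts were 995, 1385, 1733 and 810 for DEP, DProP, DPP and Mix against vehicle. They were 16, 137, 23, 99, 245 and 576 for DEP against DProP, DEP against DPP, DProP against DPP, and Mix against DEP, DProP and DPP, and 557 for all 4 treatments. DESeq2 called 580, 1110, 384 and 1361 genes in DEP against DProP, DEP against DPP, DProP against DPP and Mix against DEP. A fit of the 2 groups alone called 489, 979, 17 and 1602 there, and the GC and length correction 253, 1036, 203 and 1219. The stricter filter called 279 genes in DEP against DProP and 146 in DProP against DPP. Genes called in all 4 treatments numbered 3322 with library size alone and 1436 with the GC and length correction.

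Leaving out 1 library gave 2075 to 3206, 3976 to 4998, 4343 to 6038 and 1569 to 2902 genes for DEP, DProP, DPP and Mix against vehicle. It gave 9 to 267 for DEP against DProP, 80 to 747 for DEP against DPP and 5 to 132 for DProP against DPP. For Mix it gave 33 to 414 against DEP, 382 to 774 against DProP and 1498 to 2676 against DPP. In all 4 treatments the range was 1148 to 2084. The lowest counts came without DEP 1, DProP 2, DPP 2 and Mix 1 against vehicle, without DEP 2 (DEP against DProP and DPP), DPP 2 (DProP or Mix against DPP), DEP 1 (Mix against DEP) and Mix 1 (Mix against DProP, and all 4).

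With the replicate number as a block, the counts against vehicle were 4301, 5977, 6780 and 3699 for DEP, DProP, DPP and Mix. Between treatments they were 92, 529, 36, 651, 1234 and 3147 in the order given above, and 2033 for all 4 treatments.

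Lists called against vehicle numbered 14, 17, 20 and 14 for DEP, DProP, DPP and Mix. With an estimated correlation they were 3, 3, 3 and 2, and fry called 22, 28, 26 and 18. The named genes gave 738 pairs of gene and comparison and 10661 values under alternatives. In 9821 of these the direction and the call were kept, in 840 the call was lost, and 0 reversed in edgeR, limma-voom or DESeq2. The pairs were chosen as past the threshold in these same libraries, so a reversal was unlikely from the start and its absence is no support. Most of the lost calls came from fits that left out a library. Against vehicle, library size alone moved the balance of calls to 4794 higher and 1259 lower in DEP, 5850 and 1699 in DProP, 5820 and 2200 in DPP, and 4605 and 1020 in Mix. The cell cycle list, higher in DProP than in DPP, was reversed without DProP 2 (adjusted p = 1.02e-05) and lost its call without DPP 1 (adjusted p = 0.0607). On simulated data with this depth and 2 libraries per group edgeR called 30.9% of genes shifted by 0.5 on the log2 scale. Few genes were shifted there, 68, 65 and 63 by 0.5, 1 and 2 beside 18831 unshifted. The adjusted threshold was therefore harder to pass than against vehicle, where 20.4% to 36.2% of tested genes were called. The share of small changes missed in these data was not measured. Depth was not varied, and the spread between libraries of a group, with a chi-square per degree of freedom from 11.3 to 21.7, exceeded counting error.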

Other observations

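The tests of the GC trend and of a batch in the vehicle comparisons, and of the share of neurons, were chosen only after the result was seen. For the others the predictions were written before the test. The neuronal and cholesterol patterns themselves were taken from list tests between treatments, which were added after the data were seen. The GC and length correction was also chosen after the data were seen. No measurement outside these libraries was used here.

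The 8 treated libraries differed from the 2 vehicle libraries across RNA classes, with 1157 protein-coding genes lower in all 4 treatments. The GC and length correction argues against a GC trend as the whole cause for these genes: 56.3% of the 1155 with a GC value stayed lower in all 4 (650), and 264 of 462 higher ones stayed higher. The bound for this test was also set after the result was seen. The remaining genes lost a call, so a GC and length trend as a part of the cause stays open. Captured genomic DNA was weighed for the noncoding genes that were higher. Olfactory receptor genes took at least 1.21 times the vehicle share of counts in every treated library. That lies between the bounds of 1.1 and 1.5 set beforehand, so the ratio leaves this undecided. Only 43 to 62 of the 380 olfactory receptor genes had a count in a library, so the share rests on few genes. DNA caught across them might be expected to reach more of them, which argues against this explanation only as far as these genes were captured and their reads counted. The number that such DNA would reach was not computed. A batch that coincides with vehicle cannot be told apart from treatment, because no label separates them, and the first principal component, with 35.4% of the variance and vehicle at -73.7 and -74.5 against -5.03 to 46.7 in treated libraries, would set vehicle apart under either. An effect common to all the phthalates stays open as well, untested.

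Neuronal markers had a lower median in DPP than in DEP, a call that was lost with an estimated correlation (adjusted p = 0.0656 with an estimated correlation). The direction did not rest on 1 DPP library. The median of DEP over DPP was 0.34 without DPP 2 and 0.68 without DPP 1, against 0.45 with both. Its size thus depended on the DPP library. The list was chosen in these same libraries, so a loss of the direction was unlikely from the start. A GC trend is argued against, since the median was 0.44 after its removal. A smaller share of neurons might lower these genes together and would raise markers of other cell types. Their lowest median of DPP over DEP was -0.0731 in progenitor markers (95% interval -0.104 to 0.0305 from 2000 resamples of the list's genes, which holds no spread between libraries), with intervals of -0.195 to 0.0192 for astrocyte and -0.664 to 0.407 for oligodendrocyte markers, which leaves a share of neurons and lower expression per neuron open. NEFL, which was higher in DPP than in DEP, moved against the list median.

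Cholesterol synthesis genes had a higher median in DProP than in DEP. A smooth GC and length trend does not account for this: the median of DEP over DProP was -0.53 after the correction, against -0.51 without it. The value nearest 0 without 1 of the 4 libraries was -0.48. The list was chosen in these same libraries, with mean centred log2 CPM of -0.222 and -0.186 in DEP and 0.273 and 0.324 in DProP. A loss without 1 library was thus unlikely from the start, and its absence is no further support. A culture or library batch that differs between DEP and DProP cannot be told apart from treatment. With LXR targets lower in DProP, a candidate explanation is a lower sterol level in DProP-treated cells, which would raise SREBF2 targets and lower LXR targets. Sterols were not measured in these data, so this hypothesis was not tested.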
